A study of Mus musculus with 2 samples.

How the data were processed

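The data are 2 single-cell libraries, 1 from control water and 1 from metformin in drinking water, of cells sorted for high CD45 from the dissected tumour region of C57BL/6 mice on day 20 after intracranial injection of GL261 cells, made with the 10x Genomics Single Cell 3' v3 kit per the labels' protocols. The labels do not give the number of mice per library, their sex, the metformin dose or the sort gates. Per the submitters' processing notes, Cell Ranger and Seurat were used with the genome build mm10, and per the file headers the matrix software version was 3.0.0. The aligner settings and the annotation used for counting were not given in the sources used here. The deposited values are UMI counts per gene and barcode, whole numbers for 31053 genes in 6174 control and 5473 metformin barcodes. Each barcode had at least 500 UMIs. Every cell class below was rebuilt from the counts, so it may differ from the classes of the study.

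Barcodes with fewer than 300 detected genes (92 control and 151 metformin) or more than 10% mitochondrial UMIs (727 and 856, 11.8% and 15.6% of barcodes) were left out, leaving 5435 and 4606. Doublets were called per library with Scrublet as built into scanpy, with an expected rate of 5%. It marked 62 (1.14%) and 37 (0.803%) cells, which were removed, leaving 5373 and 4569 cells with 46751843 and 44088764 UMIs. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen, and 30 principal components of values clipped at 10 and 15 neighbours were used for Leiden clustering of both libraries together, without batch correction. The genes of the hypoxia, cell cycle, stress, interferon and cAMP lists and mitochondrial, ribosomal, haemoglobin and sex-linked genes were kept out of the variable genes. Resolution was 1.0 for all cells and 1.5 for a second clustering of T, NK and innate lymphoid cells.

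The 36 clusters were read against markers of 27 cell types fixed in advance and called "like" a type only where at least 3 of its markers were detected and the 10 leading genes did not go against it. This gave 27 classes, of which 18 carry a cell type name and the others are named by leading genes. Of the CD8 T-like clusters, cluster 5 was led by the interferon genes Ifit3, Ifit1 and Mx1, cluster 4 by Nr4a2 and Nr4a3, and cluster 14 by Gzmg, Gzmd and Gzme. In the metformin CD8 T-like cells, 1 cell of cluster 14 held at least 99.8% of the UMIs of each of Gzmg, Gzmd and Gzme. Of the CD4 conventional T-like clusters, cluster 9 was led by Csf1, cluster 12 by Ccl1 and Il2, and cluster 16 by Slfn5 and Adk. Unnamed clusters held 139 control and 161 metformin cells (2.59% and 3.52%) and were compared by share only. The word like is left out after the first mention of a class. γδ T cells were also taken by a gate of at least 2 Trdc UMIs and at least 1 UMI of Cd3d, Cd3e or Cd3g among T, NK and innate lymphoid cells.

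With 1 library per group no test was run and no p-value is given, and cells were not treated as replicates. Shares of cells carry exact Clopper-Pearson intervals. UMIs were summed per library and class and given as counts scaled to that sum (CPM), with exact Poisson intervals, and ratios of metformin over control carry exact conditional intervals. All intervals are at 95% and cover counting error only, not differences between animals or sorts. The intervals of CPM, gene ratios and list medians treat every UMI as independent. They therefore do not cover the spread between cells of a class either. Log2 ratios use 0.5 UMI added to each sum, and a ratio against 0 UMIs is given as at least the fold over a floor of 3 UMIs. The precision follows the depth: the γδ T cluster held 65 and 50 cells with medians of 6594 and 6674 UMIs, so Klrk1 had 39 and 41 UMIs there, against 1904 and 2194 in CD8 T cells. For shares of cells with a UMI, each cell was thinned to the 10th percentile of UMIs of the shallower library in its class and shallower cells were left out (7 and 6 γδ T cells, 60 and 37 CD8 T cells, 33 and 56 NK cells).

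Genes were named by a fixed rule of size in the 14 classes with at least 50 cells in each library. A gene needed at least 50 CPM and 20 UMIs in 1 library, a ratio of at least 1.5 either way and an interval without 1. Genes were ranked by the interval bound nearest to 1. The 10 highest and 10 lowest were taken in γδ T cells, CD8 T cells and microglia, the largest myeloid class, and the 5 highest and 5 lowest elsewhere. Immunoglobulin and T cell receptor segment genes, mitochondrial, ribosomal, haemoglobin and sex-linked genes and predicted genes were left out. A set of fixed genes was always given in γδ T, CD8 T and NK cells and in microglia, and up to 4 members of each list with the bound farthest from 1 could be named. Trac, Trdc, Ide, Fgfbp3 and their neighbours, and the genes of RNA outside cells, were singled out after their values were seen where the rule did not name them. Some genes that met the rule are not reported here.

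Gene lists were fixed in advance: hypoxia and glycolysis, complex I, complexes II to V, mitochondrially encoded genes, NKG2D and cytotoxicity, IL-17 programme, cAMP and CREB response, apoptosis, checkpoint and exhaustion, naive and memory, cell cycle, type I interferon, interferon-gamma, MHC class II, suppressive and repair, inflammatory myeloid, adenosine pathway, NKG2D ligands, AMPK, integrated stress response, and mTORC1 and Myc, with checks of dissociation and stress, haemoglobin, and neutrophil, macrophage and glial transcripts. A list member needed at least 10 UMIs over both libraries in the class. The value is the median log2 ratio of the members, with an interval from 1000 resamplings of the counts, and its percentile among 10000 random lists of the same size matched on expression describes these 2 libraries only. Coordinates are those of GRCm38 (mm10) with the GENCODE vM21 annotation.

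The filters, clustering settings, lists, markers and the naming rule were chosen before the data were examined. So were 39 alternatives, and 3 were added later, with a setting counted again for each kind of result it was applied to. They changed the cell filter (none, or at least 1000 genes and at most 5% mitochondrial UMIs), the treatment of doublets, the resolution (0.6 and 1.0, or 1.5 and 2.0), the variable genes, joint or separate clustering, the denominator, the γδ T definition, the scaling, the weight of deep cells, thinning, the pseudocount of 2 UMIs and the minimum of 50 or 1 UMIs for list members. The names of clusters were given after clustering.

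The gene and list scripts were tested on simulated data drawn from the pooled means and depths of 3 classes, with 50 genes changed at each fold. At 2-fold up, 96.0% of changed genes met the ratio and interval parts of the size rule in CD8 T cells (8981 genes), 84.0% in γδ T cells (2331 genes) and 98.0% in microglia (9421 genes), and at 2-fold down 96.0%, 78.0% and 86.0%. Of unchanged genes, 121 of 8781, 86 of 2131 and 109 of 9221 met them. The simulated class sums had Poisson spread only, so genes with most UMIs in few cells were not covered by these counts. Of 200 unchanged lists, 6.5%, 6.0% and 6.0% fell outside the central 95% of random lists. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, with random seed 0.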

Results

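Immune cells were taken from brain tumours of C57BL/6 mice after an intracranial injection of GL261 cells, a mouse glioma line. The mice had drunk either control water or water with metformin, a biguanide known to inhibit mitochondrial complex I and so to lower oxygen use. On day 20 the tumour region was dissected and cells with high CD45, a surface protein of blood-derived immune cells, were sorted and sequenced as single cells by 10x Genomics 3' chemistry. The title of the series names tumour hypoxia and γδ T cells. The comparison asks how the composition and the transcripts of these cells differ between the control and the metformin library, first in γδ T cells and then in the other classes. Each group was 1 library, so no difference has a replicate check and no test of the treatment was possible. The control library held 6174 barcodes with 49651404 UMIs (median 6762 per barcode) and the metformin library 5473 barcodes with 47142356 UMIs (median 7098). After filtering, 5373 and 4569 cells were retained, with medians of 7295 and 7926 UMIs. Intervals below are 95% intervals that cover counting error only, and a ratio is always metformin over control. Those of genes and lists also leave out the spread between cells of a class.

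The metformin library held a smaller share of B cells and a larger share of NK cells and dendritic cells than the control library. B-like cells made up 12.3% of control cells and 5.49% of metformin cells (ratio 0.447, interval 0.385 to 0.517). NK-like cells, innate lymphocytes that kill target cells, made up 7.45% and 12.3% (ratio 1.65, interval 1.45 to 1.88). CD4 conventional T-like cells were at 11.2% and 8.08% (ratio 0.722, interval 0.633 to 0.823), and CD8 T-like cells at 11.2% and 12.6% (ratio 1.13, interval 1.01 to 1.27). Regulatory T-like cells, which restrain other T cells, were at 5.27% and 6.04% (ratio 1.15, interval 0.968 to 1.36). Conventional dendritic cell-like cells, which present antigen to T cells, were at 1.79% and 3.15% (ratio 1.76, interval 1.35 to 2.31). Mature dendritic cell-like cells were at 0.819% and 1.53% (ratio 1.87, interval 1.27 to 2.79) and plasmacytoid dendritic cell-like cells at 0.372% and 0.766% (ratio 2.06, interval 1.16 to 3.76). Neutrophil-like cells numbered 45 and 6 (ratio 0.157, interval 0.0547 to 0.369) and basophil-like cells 19 and 3 (ratio 0.186, interval 0.0352 to 0.631). There were 96 and 49 monocyte-like cells (ratio 0.60, interval 0.417 to 0.855). Macrophage-like cells were at 7.09% and 7.90% (ratio 1.11, interval 0.962 to 1.29). Microglia-like cells, the resident macrophages of the brain, were at 15.3% and 12.2% (ratio 0.799, interval 0.716 to 0.890), a share that the CD45 sort can set because microglia carry less CD45 than blood-derived cells. The C4b/Ccl12 microglial cluster, counted apart, held 415 and 407 cells (ratio 1.153, interval 1.003 to 1.325). The Il1a/Hmox1 microglial cluster, also counted apart, held 85 and 64 (ratio 0.8854, interval 0.6299 to 1.239). The lower share of microglia-like cells therefore does not stand for all microglial cells. The lymphoid classes together differed little, at 58.4% and 57.2% of cells (ratio 0.979, interval 0.929 to 1.031). With each library clustered on its own, the conventional dendritic cell ratio was 0.983, and with a stricter cell filter the B cell ratio was 0.280.

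**Figure D1:**
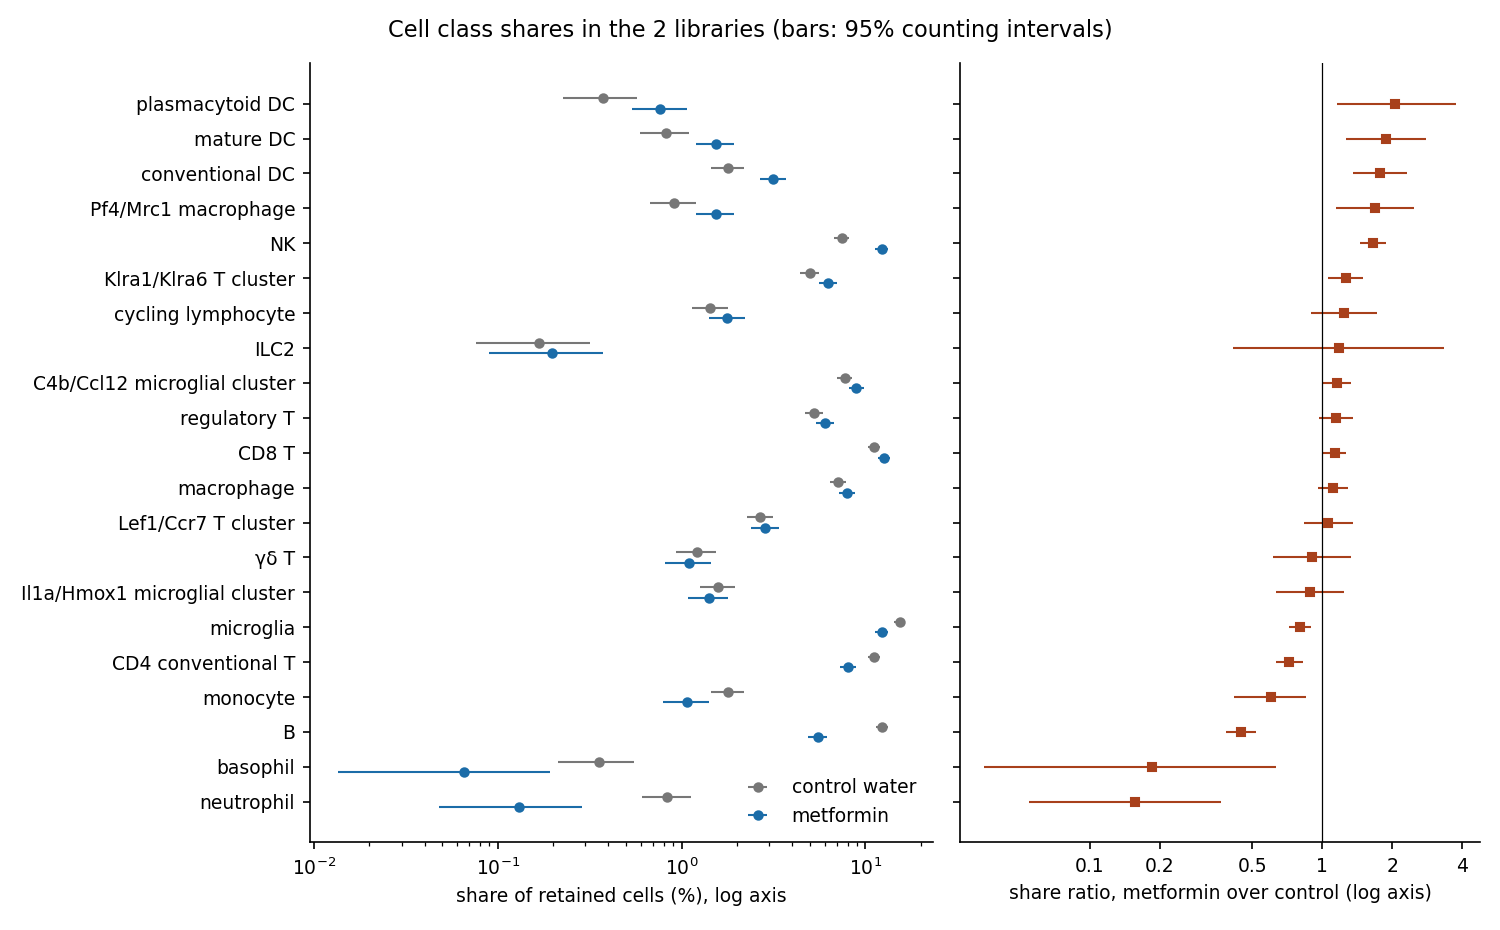
Share of retained cells in each class in the control and metformin libraries (left, percent on a log axis) and the ratio of the shares (right, log axis); bars are 95% counting intervals, with 1 library per group. NK cells lie above a ratio of 1 at 1.65 and B cells below it at 0.447.

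γδ T cells carry a T cell receptor of γ and δ chains, and NKG2D, encoded by Klrk1, is a receptor by which they and NK cells recognise stressed cells. The γδ T-like cluster held 65 control and 50 metformin cells, 1.21% and 1.09% of retained cells (ratio 0.905, interval 0.613 to 1.33). Its share did not differ beyond counting error, but the ratio was 0.571 with the stricter cell filter. Its leading genes were Il17a, Cd163l1, Tcrg-C1 and Trdc, a profile of IL-17-producing γδ T cells. After thinning to 4237 UMIs per cell, Trdc, the constant segment of the δ chain (chromosome 14, 54142851 to 54148868), had a UMI in 51.7% and 63.6% of its cells. For Trac, the constant segment of the α chain, it was 48.3% and 52.3%. In B cells at the same depth Trac had a UMI in 4.13% and 3.50%, so the cluster also held cells with α chain transcripts. Trac was lower in the metformin cells (351 and 204 CPM, counts scaled to the total UMIs of the class, ratio 0.581, interval 0.428 to 0.780). γδ T cells were therefore also picked by transcript, as T, NK and innate lymphoid cells with at least 2 UMIs of Trdc and at least 1 UMI of Cd3d, Cd3e or Cd3g. This gate took 101 control and 121 metformin cells, 1.88% and 2.65% (ratio 1.41, interval 1.07 to 1.85). Of its 222 cells, 66 lay in the γδ T-like cluster (34 control and 32 metformin), 112 in a T cell cluster led by the receptor genes Klra1 and Klra6 (47 and 65, ratio 1.63, interval 1.10 to 2.42) and 33 in NK-like clusters (13 and 20).

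Within γδ T cells, Bcl2, which protects cells from apoptosis, was lower in the metformin library, and the transcripts of NKG2D and its adaptor did not differ beyond counting error. Klrk1 (chromosome 6, 129610323 to 129623864) was at 89.4 and 127 CPM in the cluster (ratio 1.42, interval 0.890 to 2.25) and at 334 and 363 CPM in the gate (ratio 1.09, interval 0.923 to 1.28). Hcst, the adaptor DAP10 that passes on the NKG2D signal, had a ratio of 0.994 (interval 0.796 to 1.24) in the cluster. After thinning, 27.6% of control and 31.8% of metformin cells of the cluster had a Klrk1 UMI (30.8% and 38.0% unthinned), beside 1.5% and 2.0% of B cells, which should lack it. Median depths were 6594 and 6674 UMIs in the cluster and 5635 and 5241 in B cells. Bcl2 (chromosome 1, 106538178 to 106714274) was at 170 and 83.3 CPM in the cluster (ratio 0.491, interval 0.304 to 0.772) and had a ratio of 0.835 (interval 0.731 to 0.954) in the gate. Gzmb, encoding the killing protease granzyme B, had 15 and 20 UMIs in the cluster (ratio 1.79, interval 0.873 to 3.77) and 397 and 545 CPM in the gate (ratio 1.37, interval 1.19 to 1.58). The gated cells within the γδ T-like cluster had 4 and 15 Gzmb UMIs (ratio 3.98, interval 1.27 to 16.5). Those within the Klra1/Klra6 cluster had 88 and 135 (ratio 0.957, interval 0.727 to 1.27). The whole gate held 303 and 553, so most of its Gzmb UMIs came from gated cells in NK-like and other clusters. The same held for Klrk1, with 255 and 368 UMIs in the gate but 29 and 24, and 80 and 145, in these parts. In the gate 1 cell held 31.4% of control and 1 cell 24.8% of metformin Gzmb UMIs. Il17a, the main cytokine of these cells and the gene leading the cluster, had a ratio of 1.02 (interval 0.866 to 1.19), and 0.831 (interval 0.688 to 1.0) without the richest cells. Ifng had only 2 and 1 UMIs. Hif1a, the oxygen-sensing transcription factor, had ratios of 0.825 (interval 0.612 to 1.11) and 1.28 (interval 0.945 to 1.73) in cluster and gate. In the 66 cells that met both definitions it was higher, with a ratio of 1.72 (interval 1.06 to 2.83), while Bcl2 had 0.544 (interval 0.305 to 0.942) and Klrk1 0.878 (interval 0.490 to 1.56) there. Il17a had 1.28 (interval 1.07 to 1.54) in the same cells, and 1.2 (interval 0.955 to 1.5) without the richest cells. Ldha, a glycolytic enzyme, had 0.913 and 1.07, and Crem, a gene induced by cAMP, 0.911 and 0.962. Pdcd1, the checkpoint receptor PD-1, had 0.938 in the cluster and 0.730 (interval 0.548 to 0.972) in the gate. The gated cells of the γδ T-like cluster had 0.696 (interval 0.496 to 0.972), and those of the Klra1/Klra6 cluster 3.23 (interval 1.33 to 9.45) on 6 and 31 UMIs. Without the richest cells the latter was 2.26 (interval 0.810 to 7.80), so its direction was not settled.

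**Figure D2:**
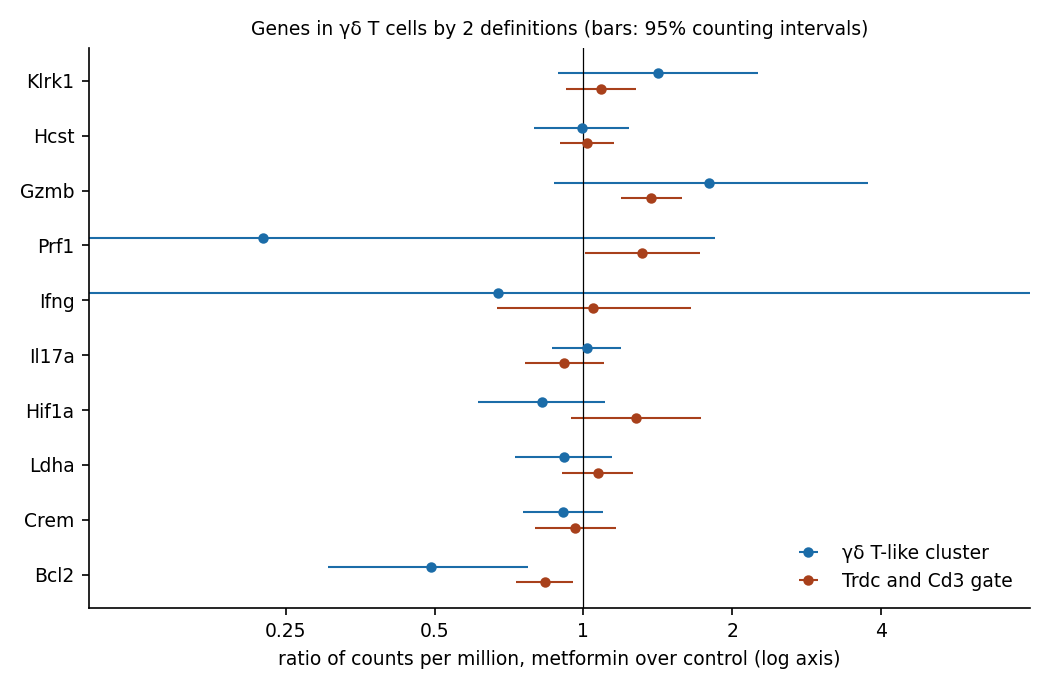
Ratio of CPM, metformin over control (log axis), of 10 fixed genes in the γδ T-like cluster (65 and 50 cells) and in the cells of the Trdc and Cd3 gate (101 and 121 cells); bars are 95% counting intervals, and those of Prf1 and Ifng in the cluster run past the axis. Bcl2 lies below 1 in both definitions, and the intervals of Klrk1, Hcst and Ldha include 1.

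In the γδ T-like cluster, 102 of 2822 eligible genes were higher and 115 lower by the fixed rule of size. Without the richest cells 69 and 101 remained. In the simulation of this class, on a gene set drawn by another cutoff, 86 of 2131 unchanged genes met the ratio and interval parts. A sizeable part of the genes named here could thus arise from counting alone. Other genes higher in the metformin cells of the cluster included S1pr1, a receptor for exit from tissue (29.8 and 117 CPM, ratio 3.93, interval 2.05 to 8.05). Higher too were the MHC class II genes H2-Aa (ratio 5.0, interval 2.11 to 13.6) and Cd74 (ratio 2.77, interval 1.83 to 4.24), and Ccdc88b, Axin1, Myadm and Slc25a36. H2-Aa had only 7 and 26 UMIs, and markers of plasmacytoid dendritic cells were higher as well (ratio 1.46, interval 1.18 to 1.82), so class II transcripts from other cells are not ruled out. All 32 metformin UMIs of Il22, an epithelial repair cytokine, came from 1 cell. Lower genes included Il17f (35 and 2 UMIs, ratio 0.0769, interval 0.00896 to 0.299) and the TNF family ligands Tnfsf8 (33 and 1 UMIs, ratio 0.0408, interval 0.0010 to 0.244) and Tnfsf11 (ratio 0.349, interval 0.222 to 0.533). Lower too were Zeb2 (ratio 0.138), Eea1, Ptms and Iigp1 (ratio 0.294). Cd4, a marker of another T cell class, was also lower (39 and 6 UMIs, ratio 0.207, interval 0.0716 to 0.493). Of the 32 measured hypoxia and glycolysis genes, 1 was higher and 1 lower by the size rule, with a median log2 ratio of -0.00 (interval -0.16 to 0.14). The median of the NKG2D and cytotoxicity list was 0.07 (interval -0.14 to 0.39) and that of the cAMP and CREB response list 0.10 (interval -0.13 to 0.21). The IL-17 programme list had a median of 0.24 (interval 0.08 to 0.36) in the cluster and -0.22 in the gate. The interferon-gamma response list had 0.23 (interval 0.11 to 0.36) and -0.20, so both turned with the definition. In the gated cells of the γδ T-like cluster, the 2 lists had 0.21 (interval -0.0029 to 0.34) and 0.13 (interval -0.06 to 0.29). In those of the Klra1/Klra6 cluster they had -0.13 (interval -0.68 to 0.23) and -0.34 (interval -0.46 to -0.14). Cxcl10 and Helz2, higher in the cluster with ratios of 2.69 and 3.18, were lower in the gate with log2 ratios of -1.08 and -0.16. Dusp6 and Cd4, lower in the cluster with ratios of 0.122 and 0.207, had log2 ratios of 0.06 and 0.69 in the gate.

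In CD8 T-like cells, the cytotoxic T cells, Tox, Bcl2 and Pdcd1 were lower in the metformin library while Klrk1 and Ifng differed little. Marker sets of other cell types differed in this class too, with the NK set at a ratio of 0.782 (interval 0.770 to 0.795), the γδ T set at 1.64 and the monocyte set at 1.22. The NK set holds Gzma and Prf1 and the monocyte set holds Ly6c2. Gzma and Ly6c2 were among the leading genes of CD8 T clusters. The NK and monocyte ratios therefore cannot tell transcripts of other cells from those of the CD8 T cells themselves. Tox, a transcription factor of exhausted T cells, was at 85.9 and 47.1 CPM (ratio 0.548, interval 0.471 to 0.637). Pdcd1 (chromosome 1, 94038305 to 94052553) was at 260 and 218 CPM (ratio 0.838, interval 0.776 to 0.904), and Bcl2 rested on 1399 and 1203 UMIs (ratio 0.761, interval 0.704 to 0.822). Of 20 measured checkpoint and exhaustion genes 2 were lower and 0 higher by the size rule, and the median was -0.19 (interval -0.26 to -0.10). Its members Lag3 and Ikzf2 had ratios of 0.727 (interval 0.680 to 0.777) and 0.759 (interval 0.665 to 0.866), and Tox2 0.170 on 26 and 5 UMIs. Klrk1 was at 358 and 365 CPM (ratio 1.02, interval 0.959 to 1.08), and after thinning to 3771 UMIs had a UMI in 57.5% and 61.5% of cells (66.4% and 73.3% unthinned), beside 1.17% and 2.29% of B cells. The ratios of Hcst and Ifng were 1.06 (interval 1.02 to 1.10) and 1.08 (interval 1.0 to 1.17). Gzmb (chromosome 14, 56258838 to 56262260) had 0.926 (interval 0.901 to 0.951). Prf1, encoding the pore-forming protein perforin, had 0.914 (interval 0.851 to 0.983), and 0.573 without the cell richest in it in each library, since 1 metformin cell held 42.8% of its UMIs. Nr4a1, a gene induced by receptor signalling, had 0.738 (interval 0.618 to 0.882), and Mki67, a marker of dividing cells, 0.698 (interval 0.551 to 0.883).

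Among the other CD8 T cell genes lower in the metformin library by the size rule were Cxcl10, a chemokine induced by interferon (65.4 and 32.4 CPM, ratio 0.496, interval 0.414 to 0.593), and the costimulatory receptor Tnfrsf4 (ratio 0.517, interval 0.423 to 0.631). So were the transcription factors Irf8 (ratio 0.628) and Maf (ratio 0.666), Cd6 (ratio 0.659) and Il18rap (ratio 0.659). The metallothioneins Mt1 and Mt2, which bind metal ions, were higher with ratios of 2.87 and 3.34, and 1.61 and 1.91 without the richest cell. Lgals3 had a ratio of 1.56 (interval 1.45 to 1.67). Gzmd, Gzmg and Gzme were at least 1969-fold, 1502-fold and 688-fold higher against a floor of 3 UMIs, and Gzmc and Spp1 6.46 and 29.7 times higher. These 5 genes had at least 95.9% of their metformin UMIs in 1 and the same cell, which held 159560 UMIs and was not marked by the doublet caller. Without the richest cell of each library Gzmc and Spp1 had ratios of 0.353 and 0.412, and Tyrobp and Il2ra 0.978 and 1.15. Of 48 measured cell cycle genes 9 were higher and 0 lower (median 0.26, interval 0.19 to 0.37), among them Rrm2 (ratio 2.37) and Mcm2 (ratio 1.54), both used in DNA replication. With variable genes drawn from all genes, this median was -0.20. The integrated stress response list, of genes induced when translation is held back, had a median of -0.18 (interval -0.25 to -0.06), and Ddit3 a ratio of 0.788 (interval 0.660 to 0.940). The naive and memory list had -0.09 (interval -0.19 to 0.01) and the apoptosis list -0.05 (interval -0.12 to 0.03). Most control cells of this class lay in lymphoid clusters 5 and 14 (206 and 174 cells) and most metformin cells in clusters 14 and 5 (219 and 151 cells).

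NK-like cells of the metformin library had more transcripts of Nr4a1, Fos and Dusp1, which stimulation induces within minutes, and differed little in Klrk1. Nr4a1 (chromosome 15, 101254269 to 101274795) was at 63.4 and 113 CPM (ratio 1.79, interval 1.5 to 2.14). Fos was at 179 and 289 CPM (ratio 1.62, interval 1.45 to 1.80) and the phosphatase gene Dusp1 at 89.3 and 137 CPM (ratio 1.53, interval 1.32 to 1.79). Of 21 measured cAMP and CREB response genes 4 were higher and 0 lower, with a median of 0.21 (interval 0.09 to 0.32). Lymphoid cluster 6, with Nr4a2 among its leading genes, held 13.5% of control and 20.4% of metformin NK cells (ratio 1.51, interval 1.08 to 2.13). Fos, Dusp1 and Atf3 are also on the dissociation and stress list, which tracks handling of the tissue and had 3 of 26 members higher and 0 lower (median 0.13, interval 0.10 to 0.21). Klrk1 was at 984 and 1007 CPM (ratio 1.02, interval 0.974 to 1.07), with a UMI in 92.1% and 94.4% of cells after thinning. Gzmb had a ratio of 0.955 (interval 0.912 to 0.999), Prf1 0.945 (interval 0.879 to 1.02), Ifng 1.12 (interval 0.954 to 1.31) and Bcl2 0.859 (interval 0.804 to 0.919). Jaml, a junction adhesion molecule, was lower (ratio 0.530, interval 0.425 to 0.659), as were Ifi27l2a (ratio 0.588), Lgals3 (ratio 0.596), the chemokine gene Ccl4 (ratio 0.665) and the death ligand gene Tnfsf10 (ratio 0.625). Apoe, a macrophage transcript, was higher (ratio 2.29, interval 1.90 to 2.77). The macrophage transcript list had a median of 0.59 (interval 0.22 to 0.77), so the Apoe value cannot be read as expression by NK cells.

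The other T cell classes differed from each other. In regulatory T-like cells, Gzmb was at 1079 and 2496 CPM (ratio 2.31, interval 2.2 to 2.43) and Areg, the growth factor amphiregulin, at 125 and 277 CPM (ratio 2.21, interval 1.91 to 2.56). Markers of NK cells (ratio 1.53), γδ T cells (3.92) and mature dendritic cells (1.52, a set with Ccl5) were also higher in this class. Tbc1d4 (ratio 0.202), Cxcl10 (ratio 0.430) and Ccl3 (ratio 0.481) were lower. Gzma and the CD8 marker Cd8b1 were higher in the same class with ratios of 4.40 and 2.44, but the log2 ratio of Gzma was -0.0278 at resolution 0.6 and 1.0, against 2.13. In the Klra1/Klra6 T cluster, Fos (ratio 1.74, interval 1.55 to 1.95), Junb (ratio 1.58), Ier2 (ratio 1.62) and Nr4a2 (ratio 1.5) were higher. There the cAMP and CREB list median was 0.42 (interval 0.22 to 0.50) and the dissociation and stress list median 0.36 (interval 0.30 to 0.42). Lymphoid cluster 2, led by such genes, held 11.2% of its control and 22.7% of its metformin cells. In CD4 conventional T-like cells, 10 of 17 measured IL-17 programme genes were lower and 0 higher (median -0.83, interval -1.05 to -0.53), among them Il17a (120 and 10 UMIs, ratio 0.129, interval 0.0604 to 0.246) and Tmem176a (ratio 0.423). γδ T cell markers were higher there (ratio 1.85, interval 1.54 to 2.22), as was Ccl5 (ratio 1.72, interval 1.62 to 1.82), and Csf2, the cytokine GM-CSF (ratio 0.278, and 0.457 without the richest cells), Penk (ratio 0.336) and Nrgn (ratio 0.305) were lower. Clusters 9 and 12, led by Nrgn and Penk among others, held 208 and 207 of the 601 control cells of this class but 95 and 118 of the 369 metformin cells, while cluster 16 held 186 and 156. In cycling lymphocytes, Gzmb (ratio 2.21, interval 2.08 to 2.35) and Gzmk (ratio 2.88) were higher, and 14 of 33 cytotoxicity genes were higher and 2 lower (median 0.56, interval 0.38 to 0.67). The mix of cells in this class also differed, since markers of γδ T cells (ratio 3.41), NK cells (1.53) and CD8 T cells (1.21) were higher and those of regulatory T cells (0.777) lower. Jchain, Prtn3, Mpo, Elane and Ctsg had 1142, 529, 318, 297 and 183 control UMIs and 0 metformin UMIs there, with 67.3% to 99.1% of each in 1 cell.

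Genes of the type I interferon response, the antiviral programme, had median log2 ratios below 0 and past the matched random lists in 8 classes, farthest in macrophages, B cells and regulatory T cells, near 0 in microglia, and above 0 in cycling lymphocytes and the C4b/Ccl12 microglial cluster. In macrophage-like cells 13 of 37 measured members were lower and 0 higher by the size rule (median -0.50, interval -0.56 to -0.46). Ifit2 (chromosome 19, 34550694 to 34576419) was at 287 and 152 CPM (ratio 0.528, interval 0.482 to 0.578). Ifit3 was at 344 and 212 CPM (ratio 0.616, interval 0.569 to 0.666) and Mx1 at 135 and 74.8 CPM (ratio 0.553, interval 0.485 to 0.630). In B-like cells 11 members were lower and 1 higher (median -0.50, interval -0.55 to -0.27). Irf7 (chromosome 7, 141262706 to 141266481) was at 121 and 59.1 CPM (ratio 0.487, interval 0.392 to 0.602) and Ifit3 at 57.7 and 15.9 CPM (ratio 0.276, interval 0.180 to 0.408). Markers of other cells also differed in these B cells, with regulatory T cell markers at a ratio of 2.14, CD8 T cell markers at 1.57, plasma cell markers at 0.699 and neutrophil markers at 0.340. Regulatory T-like cells had 11 lower and 0 higher (median -0.44, interval -0.50 to -0.30), with Ifit1 and Ifit3 at ratios of 0.623 and 0.577. Each of these medians lay below all 10000 random lists matched on expression. Medians were nearer to 0 in CD4 conventional T cells (-0.25), CD8 T cells (-0.18) and NK cells (-0.14, and 0.04 with the stricter filter). Of the CD8 T cells, cluster 5, led by Ifit3 and other interferon genes, held 34.3% in the control and 26.2% in the metformin library. Within the CD8 T clusters 5, 14, 3 and 4 the medians were -0.02, -0.05, 0.19 and -0.46. Conventional dendritic cells had -0.26 (interval -0.31 to -0.18, with 6 of 37 lower and 0 higher), but 0.07 with the libraries clustered separately. The γδ T-like cluster had -0.31 (interval -0.48 to -0.02), but 0.10 with thinned cells and 0.11 with the libraries clustered separately. The cells of the gate had -0.33 (interval -0.41 to -0.17), and those of them in the Klra1/Klra6 cluster -0.41 (interval -0.60 to -0.29). Microglia had a median of -0.01 (interval -0.07 to 0.10), which ran from -0.0622 to 0.55 over the other ways of processing. The C4b/Ccl12 microglial cluster had 0.09 (interval 0.03 to 0.20). Cycling lymphocytes had 0.24 (interval 0.14 to 0.41) and the naive-type Lef1/Ccr7 T cluster 0.23 (interval -0.02 to 0.32). The interferon-gamma response list was lower in macrophages (7 of 37 lower, 0 higher, median -0.27, interval -0.31 to -0.21), with Socs1, Iigp1 and Gbp5 at ratios of 0.559, 0.535 and 0.625. It had medians of -0.17 in regulatory T cells and -0.10 in CD8 T cells.

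**Figure D3:**
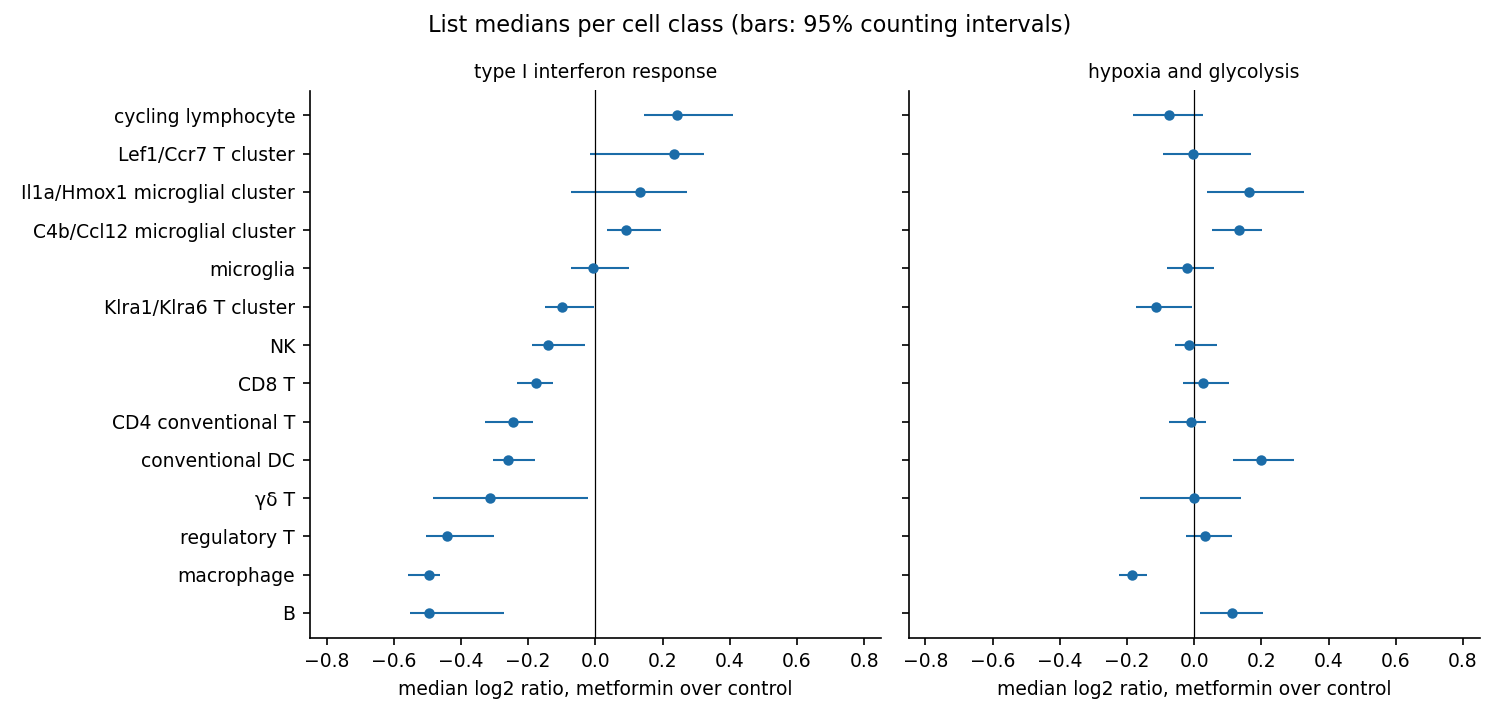
Median log2 ratio, metformin over control, of the type I interferon response list (left) and the hypoxia and glycolysis list (right) in 14 cell classes; bars are 95% counting intervals. The interferon medians of macrophages and B cells lie at -0.50 and that of microglia at -0.01, and the hypoxia median of macrophages lies at -0.18.

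The median of the hypoxia and glycolysis genes was slightly below 0 in macrophages, slightly above 0 in conventional dendritic cells and in both named microglial clusters, and near 0 in CD8 T cells, NK cells and microglia, with few members past the size rule in any class. In macrophages 4 of 38 measured members were lower and 2 higher, and the median was -0.18 (interval -0.22 to -0.14). Ero1l, an oxidase of protein folding induced by hypoxia (ratio 0.615, interval 0.508 to 0.743), Ddit4 (ratio 0.603, interval 0.471 to 0.769) and the glycolytic enzyme gene Pfkl (ratio 0.731, interval 0.639 to 0.836) were lower. Plin2, which coats lipid droplets, was higher (ratio 1.5, interval 1.4 to 1.61). In conventional dendritic cells 2 of 36 members were higher and 1 lower, and the median was 0.20 (interval 0.12 to 0.30), with Ldha at 392 and 548 CPM (ratio 1.4, interval 1.27 to 1.54). The mix of cells in this class also differed, with macrophage markers at a ratio of 0.330 and microglia markers at 0.576, which bears on all its list medians. In the C4b/Ccl12 microglial cluster 3 of 38 were higher and 1 lower (median 0.13, interval 0.05 to 0.20), and in the Il1a/Hmox1 cluster 4 of 34 were higher and 1 lower (median 0.16, interval 0.04 to 0.33). The medians were 0.03 (interval -0.03 to 0.10) in CD8 T cells, -0.01 (interval -0.06 to 0.07) in NK cells and -0.02 (interval -0.08 to 0.06) in microglia. Single members of CD8 T cells went both ways, with Hif1a (chromosome 12, 73901375 to 73947530) at a ratio of 0.837 (interval 0.760 to 0.923). Slc2a1, the glucose transporter GLUT1, was at 0.735, Ldha at 0.937 and the mitophagy gene Bnip3 at 1.88 (interval 1.27 to 2.83). The median of the nuclear genes of mitochondrial complexes II to V was slightly above 0 in CD8 T cells (0.13, interval 0.10 to 0.16), regulatory T cells (0.15), conventional dendritic cells (0.22) and macrophages (0.09), with 0 of 38 members past the size rule in each. It was also above 0 in the C4b/Ccl12 (0.17) and Il1a/Hmox1 (0.24) microglial clusters, with 0 and 1 of 38 members higher. Complex I nuclear genes had medians of 0.04 (interval 0.03 to 0.10) in CD8 T cells, 0.21 in conventional dendritic cells and 0.14 in macrophages. The mitochondrially encoded genes had 0.04 in CD8 T cells and 0.15 in macrophages. The AMPK, fatty acid oxidation and mitochondrial biogenesis list, which holds the kinase pathway that metformin is known to engage, had medians of 0.01 (interval -0.10 to 0.11) in CD8 T cells and 0.09 (interval -0.08 to 0.17) in macrophages.

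In macrophage-like cells, Cxcl2, Ccl8, Ccl12 and Gpnmb were higher and Arg1 and Chil3 lower in the metformin library. Cxcl2, a neutrophil attractant, was at 292 and 873 CPM (ratio 2.99, interval 2.81 to 3.19). Ccl8 (chromosome 11, 82115185 to 82116799) was at 62.0 and 199 CPM (ratio 3.21, interval 2.81 to 3.68) and Ccl12 at 87.8 and 209 CPM (ratio 2.38, interval 2.12 to 2.68). Arg1, encoding arginase 1, which depletes arginine (chromosome 10, 24915221 to 24927484), was at 937 and 391 CPM (ratio 0.417, interval 0.395 to 0.440). Chil3, a secreted marker of alternatively activated macrophages, was at 142 and 59.1 CPM (ratio 0.418, interval 0.363 to 0.480). Chil3 was also among the leading genes of the monocyte cluster, Ccl12 of the C4b/Ccl12 microglial cluster and Cxcl2 of the Pf4/Mrc1 macrophage cluster. Markers of other cells differed in the macrophages. Monocyte markers, which include Chil3, had a ratio of 0.742 (interval 0.729 to 0.756), mature dendritic cell markers 0.630 and microglia markers 1.4 (interval 1.32 to 1.48). Platelet markers, which include Pf4, had 1.52 (interval 1.22 to 1.90). Gpnmb, a glycoprotein of lipid-laden macrophages, was higher (62.9 and 192 CPM, ratio 3.06, interval 2.67 to 3.51), as was Lag3 (ratio 2.91, interval 2.29 to 3.73). Of 33 measured inflammatory myeloid genes 11 were higher and 1 lower (median 0.26, interval 0.21 to 0.38), among them Cxcl1 (10 and 77 UMIs) and Il6 (19 and 84 UMIs). The suppressive and repair list was split, with 3 higher and 4 lower (median -0.08, interval -0.18 to -0.03), since it holds both Gpnmb and Arg1. The mTORC1 and Myc list, of growth and ribosome assembly genes, had a median of 0.23 (interval 0.16 to 0.30). Arg1 was also the leading gene of the cluster that defines this class, and its log2 ratio was -1.31 with the libraries clustered separately.

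Microglia-like cells, the largest myeloid class, differed less than the macrophages. By the size rule Hes1, a Notch target (168 and 256 CPM, ratio 1.53, interval 1.4 to 1.67), Exosc2 (ratio 1.53, interval 1.37 to 1.71) and the pro-apoptotic gene Pmaip1 (ratio 1.59, interval 1.31 to 1.95) were higher. H2-Ab1, an MHC class II chain, was at 401 and 476 CPM (ratio 1.19, interval 1.12 to 1.26), and the MHC class II presentation list had a median of 0.11 (interval 0.02 to 0.20). Cxcl10 had a ratio of 1.30 (interval 1.19 to 1.42) and Cd274, encoding PD-L1, 0.751 (interval 0.515 to 1.08). Cxcl9 had 64 and 7 UMIs (ratio 0.166, interval 0.0642 to 0.362), with 51.6% of the control UMIs in 1 cell. Hif1a (0.933), Ldha (1.02), Bnip3 (1.01), Slc2a1 (0.815) and Mrc1 (1.01) had intervals that included 1. Only 5 of the 11 genes of the NKG2D ligand list had an entry in the counts, so the ligands were not covered as a whole. Of these, Raet1e had no UMI in either library and Ulbp1 16 and 12 UMIs, and at most 1 member of that list was measured in any myeloid class. The adenosine receptor gene Adora2b also had none, the ectoenzyme gene Nt5e 11 and 2, Vegfa 15 and 5, Arg1 4 and 1, and Nos2 2 and 1, and the adenosine pathway list had a median of -0.09 (interval -0.18 to 0.10). In the C4b/Ccl12 microglial cluster, Spp1, encoding osteopontin, was at 98.9 and 484 CPM (ratio 4.89, and 3.41 without the richest cells), Cxcl2 had a ratio of 4.19, Fabp5 3.33 and Apoc1 3.31. Cxcl9 (ratio 0.566) and Gadd45g (ratio 0.560) were lower. There 14 of 49 cell cycle genes were higher and 0 lower (median 0.60, interval 0.43 to 0.79), with Mki67 on 16 and 67 UMIs. Markers of monocytes (ratio 2.29, interval 1.92 to 2.73), cDC2 cells (1.51) and mature dendritic cells (1.32) were also higher in that cluster. In the Il1a/Hmox1 microglial cluster, of 85 and 64 cells, H2-Eb1 (ratio 0.535, interval 0.477 to 0.60) and the interferon regulator Irf1 (ratio 0.445) were lower.

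In conventional dendritic cell-like cells, Fdps and Tuba1a were higher and macrophage-type transcripts lower in the metformin library. Fdps, an enzyme of the mevalonate pathway, was at 72.5 and 159 CPM (ratio 2.19, interval 1.76 to 2.75). The tubulin gene Tuba1a had a ratio of 2.11 (interval 1.76 to 2.55) and the glycolipid enzyme gene B3gnt5 3.0 (interval 1.98 to 4.72). C1qa (ratio 0.144, interval 0.116 to 0.179) and Cd14 (ratio 0.202, interval 0.152 to 0.264) were lower together with the macrophage transcript list (median -1.33, interval -1.49 to -1.14). Thus fewer macrophage transcripts were present in the metformin cells of this class. Of 24 integrated stress response genes 7 were lower and 2 higher (median -0.32, interval -0.47 to -0.14), among them Atf5 (ratio 0.237, interval 0.155 to 0.355) and Nupr1 (ratio 0.339, interval 0.258 to 0.442).

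B-like cells of the metformin library had, besides fewer interferon transcripts, more S100a6, a calcium-binding protein (40.7 and 109 CPM, ratio 2.67, interval 2.17 to 3.28), and more Gadd45b, a stress-induced gene (70.8 and 142 CPM, ratio 2.01, interval 1.70 to 2.37). Ahnak was higher with a ratio of 2.76, and 1.86 without the richest cells. The cAMP and CREB list was higher (4 of 22 members, median 0.23, interval 0.20 to 0.40), with Nr4a3 at a ratio of 1.69 (interval 1.30 to 2.19) and Crem at 1.45 (interval 1.24 to 1.70). The dissociation and stress list had 0.09 (interval 0.06 to 0.19) in the same cells. T cell transcripts were also higher in these B cells, with Ccl5 at a ratio of 1.98 but a log2 ratio of -0.33 without the cell filter.

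Some genes were lower in nearly every class, also in classes that cannot express them, which is the pattern of RNA from outside the cells. Gh, the pituitary growth hormone gene, had 108386 UMIs in the control library, 96.3% of them in 5 barcodes, and 54 in the metformin library. A Gh UMI was present in 18.5% to 39.6% of control cells and 0.0% to 3.13% of metformin cells of 14 classes, and Gh is not counted here among the genes of any class. Igha and Jchain, transcripts of plasma cells, followed the same pattern, and Ttr, a choroid plexus transcript, was higher in the metformin library (6966 and 45265 UMIs). The neutrophil transcript list was lower in B cells (median -3.52), CD4 conventional T cells (-2.09) and microglia (-1.82) of the metformin library, which also held fewer neutrophils. The glial and tumour transcript list had a median of -0.06 in microglia and 0.07 in NK cells, and the haemoglobin list -0.96 in microglia and 0.19 in B cells.

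Ide, encoding insulin-degrading enzyme (chromosome 19, 37268743 to 37337852), was lower in the metformin library in 8 of 13 classes by the size rule, with ratios of 0.405 to 0.761 over the classes. In CD8 T cells its ratio was 0.523 (interval 0.446 to 0.612) and in NK cells 0.454 (interval 0.364 to 0.565). Over all retained cells it was 0.564 (interval 0.526 to 0.606). Fgfbp3, a fibroblast growth factor binding protein gene on the same chromosome (36917550 to 36919615), had 0.565 (interval 0.469 to 0.678). Between them lie Btaf1 with a ratio of 0.753 (interval 0.689 to 0.823), Cpeb3 with 0.836 (interval 0.630 to 1.11) and March5 with 1.07 (interval 1.02 to 1.13).

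**Figure D4:**
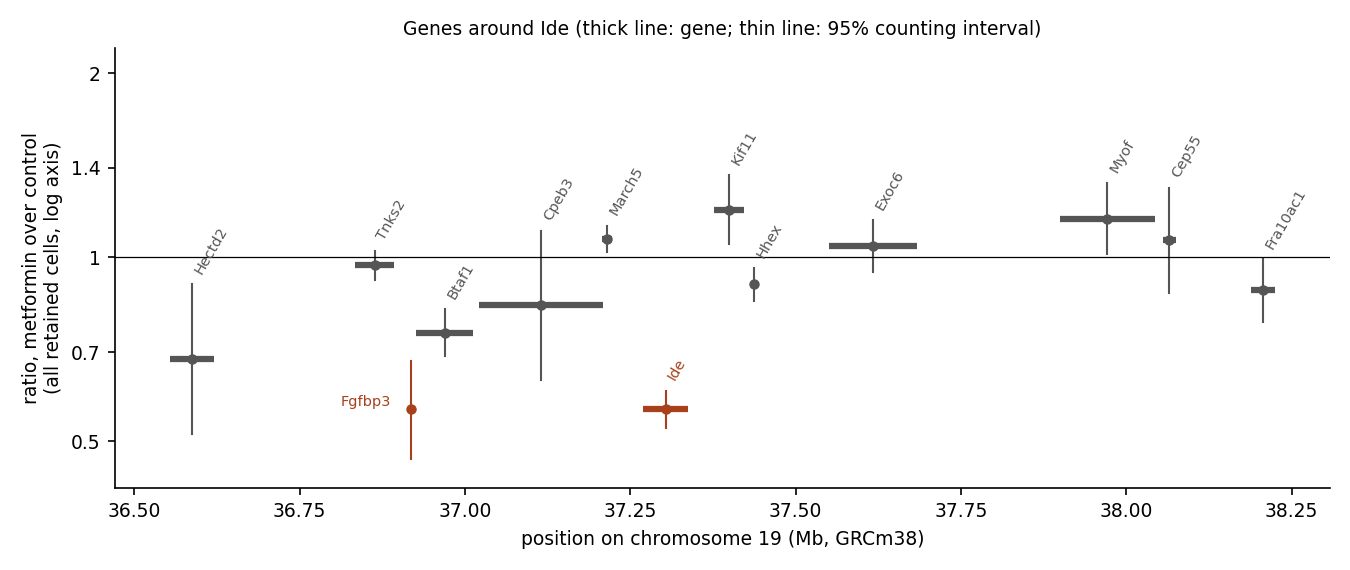
Ratio of CPM, metformin over control (log axis), over all retained cells for genes around Ide on chromosome 19 (position in Mb, GRCm38); thick lines span each gene and thin lines are 95% counting intervals. Fgfbp3 at 0.565 and Ide at 0.564 lie lowest, and March5 between them at 1.07.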

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

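For the type I interferon genes, the test of RNA from other cells was chosen only after the result was seen, and the choice of lists to compare between classes followed from the fixed lists. The results below were marked because a list lay higher in the metformin library in 1 class and lower in another, with counting intervals on opposite sides of 0. None of these differences between classes was tested, since each class has 1 library per group.

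Cell cycle genes had the widest difference, 1.88 on the log2 scale: their median was 1.72 (interval 1.10 to 2.23) in the Il1a/Hmox1 microglial cluster and -0.16 (interval -0.25 to -0.04) in CD4 conventional T cells. The value in the microglial cluster was 0.36 with thinned cells and 0.43 without the richest cell of each gene, so few cells carried most of it. IL-17 programme genes differed by 1.07, with 0.24 in the γδ T-like cluster and -0.83 in CD4 conventional T cells, but cells of the Trdc and Cd3 gate had -0.22 (interval -0.41 to -0.08). Naive and memory genes differed by 0.79, with 0.17 in B cells and -0.62 in cycling lymphocytes. The B cell value was -0.0239 with the stricter cell filter, so this contrast was lost there. Genes of suppressive and repair macrophages differed by 0.71, with 0.42 in the Il1a/Hmox1 microglial cluster and -0.29 in conventional dendritic cells. Markers of other cells also differed there. In that microglial cluster cDC2, CD4 T and CD8 T cell markers had ratios of 7.41, 3.90 and 3.59, and in the dendritic cells macrophage markers had 0.330. The mTORC1 and Myc genes differed by 0.53, with 0.23 in macrophages and -0.30 in cycling lymphocytes. Interferon-gamma response genes differed by 0.49, with 0.23 in the γδ T-like cluster and -0.27 in macrophages, but the gate had -0.20. The γδ side of this contrast and of the IL-17 contrast thus turned with the definition. Gated cells within the γδ T-like cluster had 0.13 for interferon-gamma and 0.21 for IL-17, with intervals that included 0. MHC class II genes differed by 0.46, with 0.11 in microglia and -0.35 in the Il1a/Hmox1 microglial cluster. Hypoxia and glycolysis genes differed by 0.38, with 0.20 in conventional dendritic cells and -0.18 in macrophages. The mitochondrially encoded genes differed by 0.26, with 0.15 in macrophages and -0.11 in regulatory T cells.

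Type I interferon response genes differed by 0.74, with 0.24 in cycling lymphocytes and -0.50 in B cells, and were lower in B cells, macrophages and regulatory T cells. Depth and scaling did not account for it: under 2 other scalings and thinning, the median nearest to 0 in these 3 classes was -0.31. Free RNA from other cells that lowered the list alike in every class was excluded by microglia, with a median of -0.01 (interval -0.07 to 0.10). Their lowest and highest values over all alternatives were -0.0622 and 0.55. The effect of free RNA also depends on how strongly a class itself expresses the genes. Microglia therefore cannot decide it for B cells, macrophages and regulatory T cells. The Lef1/Ccr7 T cluster decides less, with 0.23 but -0.13 as the mean of per-cell CPM. A different mix of cells within these classes was not tested and stays open. Monocyte markers had a ratio of 0.742 in macrophages, regulatory T cell markers 2.14 in B cells and NK cell markers 1.53 in regulatory T cells. A response to metformin also stays open for the 3 classes and cannot be told apart from a difference between animals, with 1 library per group.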

How the results depend on the processing

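The settings that leave out the richest cell of each gene, and the denominator without B cells, neutrophils, basophils and monocytes, were chosen only after the results were seen. Of 2830 alternative values of genes 2538 stayed within the counting interval, 275 moved beyond it and 17 turned sign. Of 3286 values of lists 3022 stayed, 248 moved and 16 turned, and of 178 share ratios 173 stayed, 4 moved and 1 turned. Of 48 UMI shares 29 stayed and 19 moved. A turn was counted only for results called higher or lower at the main value (2271, 1197 and 117 of these values). Other changes of sign were counted as moved or stayed, such as the γδ T share ratio with the Trdc and Cd3 gate. The counts of turns are therefore a lower bound on changes of sign. No paired analysis was possible because each group is 1 library and the labels give no shared replicate numbers. Clustering the libraries separately gave no share for ILC2, the Il1a/Hmox1 microglial cluster, Pf4/Mrc1 macrophages, basophils, neutrophils or plasmacytoid dendritic cells, and no gene or list value for the Il1a/Hmox1 cluster. Resolution 0.6 and 1.0 gave none for ILC2 or Pf4/Mrc1 macrophages. Depth limits the γδ T cluster most, with 65 and 50 cells. For the values below, the first is the alternative and the main value follows in brackets, as log2 unless a ratio or percent is named, and the cause was not tested except where a single cell was left out.

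With the Trdc and Cd3 gate, γδ T cells had a share ratio of 1.41 [0.905], an IL-17 median of -0.22 [0.24], an interferon-gamma median of -0.20 [0.23], Cd4 0.69 [-2.17], Cxcl10 -1.08 [1.42], Dusp6 0.0646 [-2.74] and Helz2 -0.16 [1.63]. With the stricter cell filter, share ratios were 0.280 [0.447] in B cells, 1.04 [1.26] in the Klra1/Klra6 T cluster and 0.571 [0.905] in γδ T cells. The type I interferon median was then -0.69 [-0.50] in B cells, -0.54 [-0.44] in regulatory T cells and 0.0420 [-0.14] in NK cells. In B cells the integrated stress response was 0.0281 [-0.14] and naive and memory -0.0239 [0.17], interferon-gamma in the C4b/Ccl12 cluster -0.0071 [0.06] and Gzmb in NK cells 0.0687 [-0.07]. Ccl5 in B cells was -0.31 [0.99] with doublets kept and -0.33 without a cell filter. With the libraries clustered separately, the conventional dendritic cell share ratio was 0.983 [1.76] and its type I interferon median 0.0654 [-0.26]. The γδ T medians were 0.11 [-0.31] for type I interferon and -0.25 [0.10] for cAMP, the CD8 T values 0.0827 [-0.02] for cAMP and 0.0377 [-0.29] for Crem, and the Lef1/Ccr7 values -0.13 [0.25] for cytotoxicity and -0.0319 [0.13] for interferon-gamma. Cell cycle in microglia was -0.0313 [0.20], naive and memory in CD4 T cells -0.0574 [0.10] and Jchain in B cells 1.95 [-6.21].

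With variable genes from all genes, CD8 T cells had -0.20 [0.26] for cell cycle, 0.0857 [0.04] for cytotoxicity and 0.0075 [-0.11] for Gzmb, NK cells -0.0503 [0.20] for cell cycle and microglia 0.0816 [-0.02] for hypoxia. With the mean of per-cell CPM, type I interferon was -0.65 [-0.50] in B cells and -0.41 [-0.50] in macrophages, hypoxia in CD8 T cells -0.0564 [0.03] and Ccl3 in CD4 T cells -0.14 [0.87]. With thinned cells, Ccl3 in CD4 T cells was -0.30, cytotoxicity in NK cells -0.0390 [0.01], hypoxia in macrophages -0.12 [-0.18] and type I interferon in γδ T cells 0.10 [-0.31]. NK cytotoxicity was 0.0445 under median-of-ratios scaling, Gzma in regulatory T cells -0.0278 [2.13] at resolution 0.6 and 1.0, and mTORC1 and Myc in B cells -0.0508 [0.21] at resolution 1.5 and 2.0. The cAMP median of CD8 T cells was 0.0478 [-0.02] with members of at least 1 UMI and 0.0364 without the richest cell of each gene. That last setting gave -0.65 [-0.50] for type I interferon in B cells, 1.85 [-2.09] for Gzma in conventional dendritic cells, and -1.50 [2.69], -1.25 [4.88] and -0.0331 [0.96] for Gzmc, Spp1 and Tyrobp in CD8 T cells. The percent of cells with a Klrk1 UMI, control then metformin, was 65.9 and 70.1 in CD8 T cells [57.5 and 61.5] and 98.0 and 97.6 in NK cells [92.1 and 94.4] thinned to the 25th percentile, and 66.4 and 73.3, and 97.5 and 97.3, unthinned.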

Other observations

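All tests in this part except those of metformin itself were chosen only after the results were seen. Beyond the question of the study, the Klra1/Klra6 T cluster held both T cell and innate transcripts. After thinning to 4515 UMIs, Trac had a UMI in 77.5% of its control and 65.6% of its metformin cells, Trdc in 16.2% and 23.8%, and Klrk1 in 55.0% and 52.4%. In B cells at the same depth these were 4.73% and 3.98% for Trac, 0.206% and 0.0% for Trdc and 2.26% and 2.84% for Klrk1. Its share of all cells was 4.97% and 6.26% (ratio 1.26, interval 1.06 to 1.49). Pf4/Mrc1 macrophages, with genes of border-associated macrophages, were at 0.912% and 1.53% (ratio 1.68, interval 1.15 to 2.47).

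B cells, neutrophils, basophils and monocytes made up a smaller share of the metformin library, and the cell filter was excluded, since the highest of the 4 share ratios without it was 0.543. Blood left in the tissue cannot be told apart: the naive-type Lef1/Ccr7 T cluster had a share ratio of 1.06 (interval 0.831 to 1.35), but its origin was not measured, and neutrophils (0.157) and B cells (0.447) did not share 1 ratio. Bone marrow carried over with the control tissue might add immature B cells, but the percent of B cells with an Ighd UMI was 82.8 and 83.7, a difference of 0.92 points (interval -4.48 to 6.32), although Vpreb3 had a UMI in 60.5% and 49.4%, and mature recirculating B cells are not excluded. For neutrophils, marrow cannot be told apart, with 6 cells in the metformin library, 1 of them immature, against 8 of 45 in the control library, where single cycling cells also held neutrophil precursor transcripts (Prtn3, Mpo, Elane and Ctsg, with 529, 318, 297 and 183 UMIs in that class against 0). Treatment with metformin also stays open, with 1 library per group.

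Ide was lower in the metformin library in 8 of 13 classes, and Fgfbp3 was lower over all cells. For Ide, another mix of cell classes was excluded, since the median of the Ide ratio over 13 classes was 0.571. A lower copy number of 1 unbroken segment from Fgfbp3 to Ide was excluded by March5 between them, with a ratio of 1.07 (interval 1.02 to 1.13). Copies in this region are known to vary among C57BL/6J mice. A copy-number difference of separate segments that hold Ide and Fgfbp3 but not March5 was not tested and stays open. No other explanation was tested for this pattern.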
